A study of Gallus gallus with 10 samples.

How the data were processed

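Per the labels' protocols, fertilised eggs were kept at 37 °C to Hamburger and Hamilton stage 23, the lens of 1 eye was taken out with forceps through a dorsal opening of the eyeball, and the egg was closed again. After 6 h more of incubation both retinas were dissected and stored singly. RNA was isolated with TRIzol and spin columns with DNase digestion, and stranded libraries of polyadenylated RNA were sequenced as 75 bp paired end reads on a NextSeq 500. All 10 libraries carry the same batch number (128), so no batch could be compared. Samples were grouped by their titles into 5 operated and 5 unoperated retinas, and the titles number the embryos, so that each embryo gives 1 pair and the 5 pairs are biological replicates.

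The deposited table holds normalised read counts, a signal that the authors had scaled to nearly equal totals per library (979286 to 1033235). The submitters' processing notes name the chicken build GRCg6a and FastQC 0.11.8, Trim Galore 0.6.4, HISAT2 2.1.0, SAMtools 1.9, featureCounts and Subread 1.6.2, with no role or order. The scaling method, the annotation and the counting options, including the use of strand, were not given in the sources used here. The table lists 12464 genes by symbol, of which 1202 are provisional LOC symbols. Every gene lies above 1 in at least 5 of the 10 libraries, so genes of lower expression do not enter. No coordinates are given, since no genome of the build was used.

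The depth was read from the values. In each library low values are spaced by the worth of 1 read, which gave effective library sizes of 18671000 to 26005000 reads; 1 read was worth 0.0385 to 0.0536 units. Between 89.8% and 91.6% of the values up to 400 reads were whole multiples of that step within a tolerance of 0.01, and 5.0% to 6.46% were simple fractions of it. Reads were therefore counted in part for some genes, whole reads were not recovered for 95% of values, and no count model was used. Which genes hold such fractions was not examined. At a value of 10 a gene rests on 187 to 260.1 reads, depending on the library. How much of the error of the tested genes comes from counting was not examined.

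Differences were tested with limma 3.58.1 in R 4.3.3 (a moderated linear model with an intensity trend) on log2(value + 1), with the embryo as a block, two-sided, for the 9076 genes (72.8%) with a mean of at least 10. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. A log2 change on this scale understates the change of low genes. The block follows from the titles. Deviations from the group means were correlated across genes between the control and operated libraries of the same embryo. The correlations were 0.31, 0.76, 0.45, 0.68 and 0.59 in embryos 1 to 5. In embryo 1 the best match of the control was the operated library of embryo 4 (0.34). The best match of its operated library was the control of embryo 4 (0.48). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

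Before the data were examined, the groups, the model, the alternatives, 39 gene lists and the rule for naming genes were fixed. By that rule the text names the 15 genes with the highest and the 15 with the lowest log2 change among those that passed, had the same sign in 5 of 5 embryos, a mean of at least 50 and a symbol. It names up to 4 passing members of each list in order of p, or else the 2 of highest mean. It also names 20 genes chosen in advance, of which CRYAA, CRYBB1 and MSX1 were not analysed here. Some genes that the rule selects are not reported here, and the counts of named genes over the alternatives include them. Symbols were matched exactly, and CCN1 under its older symbol CYR61. Lists with at least 5 tested members (34 of 39) were tested against all other tested genes with camera, at a preset correlation of 0.01 and with an estimated one, adjusted over the lists, and with fry. At the preset correlation 15 lists were called, and none of them with the estimated correlation. The estimated form is stricter by more than the correlation. The glycolysis list, with an estimated correlation of -0.015, went from p = 4.3e-06 to p = 0.0077 by camera. A call lost in that form therefore does not show that correlation between genes had made it. By fry, which asks whether a list's genes move on balance 1 way, 10 of these 15 passed at adjusted p under 0.05; the others were the ganglion cell, pigment, red cell, cholesterol and ribosomal protein lists. It also passed 5 lists that camera did not call: retinoic acid, endoplasmic reticulum stress and p53 and apoptosis (adjusted p = 0.027 each), and BMP ligands and receptors and cell cycle (0.041 each).

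The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, a rescaling by trimmed means, quantile normalisation, no replicate block, a robust variance prior, a minimum change of 2-fold and leaving out each embryo. After seeing the data, precision weights and covariates for pigment, mesenchyme and haemoglobin markers were added. The procedure was tested on simulated data for the operated against control comparison (9076 genes, 50 changed at each fold size). It recovered 30% of genes changed by 1.25-fold, 78% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 4 of 8876 unchanged genes were among the 156 called (2.56%). Far fewer genes were called there than in the data (2075), so the adjusted threshold was stricter in the simulation. Its genes also varied independently of each other, whereas in the data some moved together (estimated correlation 0.70 in the heat shock list). The share of 2.56% therefore does not give the error rate in the data.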

Results

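The retina was taken from both eyes of 5 chicken embryos of the Dekalb white strain at about embryonic day 4 (Hamburger and Hamilton stage 23), 6 h after the lens had been pulled from 1 eye through a dorsal slit. The other eye of each embryo was not operated on, so the series holds 5 operated and 5 control libraries of polyadenylated RNA, paired by embryo. The comparison asks which retinal transcripts depend on the lens during early growth of the eye and of its anterior part. Normalised read counts of 12464 genes were given, with column totals of 979286 to 1033235 per library. The step between low values put the effective library sizes at 18671000 to 26005000 reads. Levels below are normalised read counts as mean ± SD (n = 5 embryos per group), control first and operated second, and log2 changes are within-embryo estimates on the log2(value + 1) scale.

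At 6 h after lens removal, transcripts of 5 of 20 anterior rim genes, among them WNT2B, OTX1, GJA1 and COL9A1, and of 8 of 11 chaperones were lower in the operated retina, while 3 rim genes rose. Those of FGF8, of 3 of 11 targets of the ERK kinases (DUSP6, SPRY1 and SPRY2), of 8 of 12 Notch pathway genes and of 8 of 17 genes of glycolysis and low oxygen were higher. At the preset correlation camera called the lists of chaperones, ERK targets, Notch and glycolysis genes, but not that of rim genes (adjusted p = 0.52). None of the gene lists passed as a whole with an estimated correlation between genes, a form of the list test that is stricter by more than that correlation. The Wnt ligand WNT2B fell from 34.3 ± 16.3 to 6.63 ± 2.54 (log2 change -2.16, SE 0.24, adjusted p = 0.00075), and the fibroblast growth factor FGF8 rose from 34.2 ± 9.11 to 95.6 ± 30.3 (log2 change 1.43, SE 0.12, adjusted p = 0.00019). Of 9076 genes tested, 963 were higher and 1112 lower in the operated retinas. Most changes were small: 86.0% of these genes moved by less than 1.5-fold, 56 were at least 2-fold higher and 11 at least 2-fold lower. The within-embryo change had the same sign in 5 of 5 embryos for 1879 of the 2075 changed genes (90.6%), which a test paired by embryo favours, and for 31.9% of all tested genes, where chance gives 6.25%. The counts fell to 438 higher and 377 lower without embryo 2 and to 387 higher and 301 lower without embryo 4. They rose to 1378 higher and 1468 lower without embryo 1. When only the 4622 genes with a mean of at least 50 were tested, 412 were higher and 814 lower. The higher genes made up 33.6% of the calls there, against 46.4% in the main fit. Of genes with a mean under 10, fitted without the filter, 470 were higher and 159 lower. The balance of directions thus differed with the level of the genes. The operated eye differed from its control both in lacking the lens and in having been opened, and the design does not separate these.

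Markers of other tissues differed between the eyes as well. Pigment epithelium genes were lower in the operated libraries on average (mean log2 change of 7 genes -0.37, and -0.19 without embryo 5), as were periocular mesenchyme genes (mean of 7 genes -0.30, and -0.17 without embryo 5). The mesenchyme list was not called (camera adjusted p = 0.70, median log2 change -0.096): 2 of its genes fell, 1 rose and 4 did not pass. Without the filter on low values, 6 of 14 pigment genes were lower and 0 higher, and 4 of 15 mesenchyme genes were lower and 1 higher. Of all 12464 genes, 1262 were lower in that fit. Haemoglobin transcripts such as HBBR (41.2 ± 56.8 to 63.9 ± 32.6; 15.9 ± 3.09 to 69.6 ± 34.6 without embryo 5, n = 4) were higher in 4 of 5 operated retinas. With the pigment list's level as a covariate, chosen after seeing the data, 80 genes were higher and 9 lower; with the mesenchyme list the counts were 134 and 29, and with haemoglobin 414 and 314. Over the 2075 changed genes the log2 change was 0.894, 0.874 and 1.01 times that without the pigment, mesenchyme and haemoglobin covariate (medians), and its SE 1.77, 1.51 and 1.36 times.

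Among genes with a mean of at least 50 and a change of the same sign in all 5 embryos, 347 were higher and 708 lower. The 15 with the highest log2 change were CGTL, FGF8, NDRG1, OLFML3, SLC16A6, ECEL1, UACA, CD109, PTPRO, PLCD1, SLC6A6, MYBL1, LDHA, PTPRF and JUP. CGTL rose from 29.00 ± 3.93 to 95.4 ± 11.6 (log2 change 1.69, adjusted p = 4.5e-06) and NDRG1, a gene induced by low oxygen, from 47.7 ± 14.4 to 116 ± 23.2. OLFML3, a secreted olfactomedin-domain protein, rose from 43.6 ± 9.104 to 106 ± 23.4, and SLC6A6, the taurine transporter, from 123 ± 5.17 to 241 ± 29.7. JUP, which encodes plakoglobin, a component of cell junctions, rose from 61.2 ± 12.7 to 117 ± 23.8 (log2 change 0.92). The 15 with the lowest log2 change included NPM3, STX19, GJA1, DISP1, NOP16, SEMA3E, LAMB1, HSPH1, SLC12A2, FRY, HSPA8, RSL1D1, TIMM8A and NAT10. The gap junction protein connexin 43 (GJA1) fell from 699 ± 74.2 to 377 ± 44.2 (log2 change -0.89, adjusted p = 0.00024). DISP1, needed for release of lipid-modified hedgehog ligand, fell from 80.2 ± 19.8 to 42.6 ± 2.64, the secreted guidance factor SEMA3E from 83.01 ± 9.07 to 46.4 ± 2.81, and the laminin chain LAMB1 from 68.9 ± 22.01 to 38.6 ± 7.702. NPM3, NOP16 and NAT10, which act in the nucleolus, fell to 109.7, 43.8 and 122 from 203, 78.4 and 183.

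**Figure D1:**
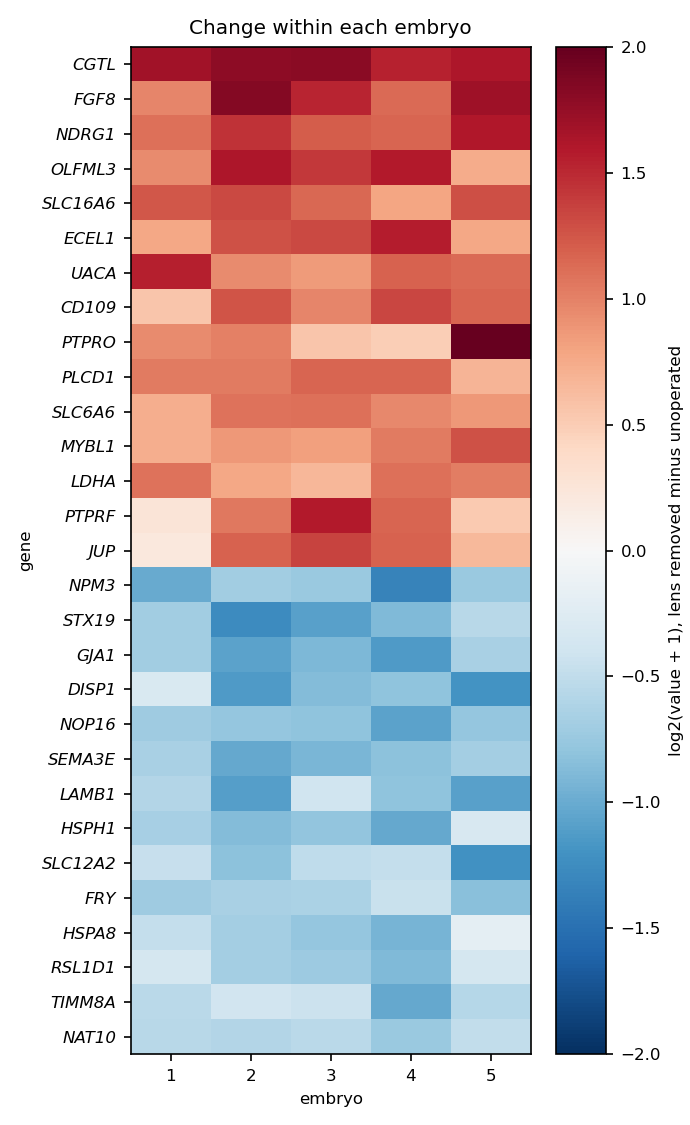
Heat map of the 29 genes named above by rule (rows) in embryos 1 to 5 (columns); colour gives log2(value + 1) in the operated minus the control retina, on a scale from -2 to 2. All 15 upper genes were higher and all 14 lower genes were lower in each of the 5 embryos, with mean log2 changes from 1.69 (CGTL) to -0.91 (NPM3).

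The anterior rim of the optic cup gives rise to ciliary body and iris. Of 20 tested rim genes, 3 rose, 5 fell and 12 did not pass (3 higher and 5 lower adjusted over the list alone). The list as a whole was not called (adjusted p = 0.52 by camera, 0.82 with an estimated correlation). OTX1, a homeobox gene of the rim, fell from 18.7 ± 6.16 to 10.6 ± 3.22 (log2 change -0.75, adjusted p = 0.002) and the collagen gene COL9A1 from 484 ± 31.9 to 345 ± 55.4 (log2 change -0.50, adjusted p = 0.0064). COL9A3, which encodes a partner chain of the same collagen, rose from 447 ± 48.5 to 592 ± 41.96. In the same libraries the pigment list changed by between -1.09 in embryo 5 and 0.03 in embryo 1, and with that list as a covariate the log2 change of WNT2B was -1.36 (adjusted p = 0.064), of OTX1 -0.77 (adjusted p = 0.14) and of GJA1 -0.89 (adjusted p = 0.044).

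Of 10 Wnt ligands, receptors and secreted inhibitors, 2 rose, 2 fell and 6 did not pass (adjusted p = 0.79; 2 higher and 2 lower adjusted over the list alone). With only genes of a mean of at least 50 camera called this list higher at the preset correlation (mean log2 change 0.22, adjusted p = 0.040). In the main fit its direction by camera was down, with adjusted p = 0.85 at an estimated correlation. WNT5A, a ligand mainly of non-canonical signalling, fell from 27.3 ± 17.2 to 10.4 ± 4.05 (log2 change -1.21), while the receptor FZD3 rose from 73.3 ± 10.6 to 103 ± 8.63. Of 9 Wnt target genes, 3 rose, 0 fell and 6 did not pass (adjusted p = 0.39; 3 higher and 0 lower adjusted over the list alone). SFRP2, which encodes a secreted Wnt inhibitor, rose from 34.8 ± 4.72 to 49.2 ± 4.56, and the feedback gene AXIN2 was at 11.02 ± 2.500 and 9.93 ± 1.43 (adjusted p = 0.45). With the Wnt genes, pigment and mesenchyme markers were lower on average, as given above, though the mesenchyme list was not called.

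Retinoic acid genes moved both ways. Of 15 tested, 4 rose, 1 fell and 10 did not pass (6 higher and 1 lower adjusted over the list alone). In the main fit the list had adjusted p = 0.11 by camera and 0.52 with an estimated correlation. With the pigment and mesenchyme covariates camera gave adjusted p = 0.031 and 0.037 at the preset correlation. The synthetic enzyme ALDH1A2 fell from 16.9 ± 5.38 to 3.29 ± 1.27 (log2 change -2.04, adjusted p = 0.00035). With the pigment covariate its change was -1.72 (adjusted p = 0.066). Its control level was lowest in embryo 1 (8.32) and highest in embryo 5 (21.9), as was that of the mesenchyme gene LUM (8.44 and 30.1). The mesenchyme list was not called (camera adjusted p = 0.70). For ALDH1A2, a fall within the retina and less mesenchyme in the operated dissections cannot be told apart. The degrading enzyme CYP26A1 rose from 12.5 ± 2.15 to 24.4 ± 4.14 (log2 change 0.92, adjusted p = 0.00087), whereas its relative CYP26C1 did not pass (9.78 ± 2.52 and 15.9 ± 5.38, adjusted p = 0.056). ALDH1A1, the dorsal enzyme of the retina, was at 703 ± 166 and 656 ± 207 (adjusted p = 0.19). CYP1B1, which can also make retinoic acid, rose from 217 ± 29.6 to 358 ± 62.8.

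Of 11 tested targets of bone morphogenetic protein (BMP) signalling, 3 rose, 1 fell and 7 did not pass (adjusted p = 0.49; 4 higher and 1 lower adjusted over the list alone). ID1, an immediate target, was at 12.4 ± 3.27 and 10.5 ± 1.47 (adjusted p = 0.19), and ATOH8 fell from 44.4 ± 3.38 to 32.7 ± 4.099. Of 11 BMP ligands, receptors and antagonists, 3 rose, 1 fell and 7 did not pass (adjusted p = 0.21; 3 higher and 1 lower adjusted over the list alone). The antagonist CHRDL1 rose from 267 ± 45.4 to 353 ± 45.02, and BMP4 was at 18.01 ± 2.63 and 18.8 ± 2.67 (adjusted p = 0.79). Among 9 genes of the TGF-beta and activin pathway, 3 rose, 2 fell and 4 did not pass (adjusted p = 0.58; 4 higher and 3 lower adjusted over the list alone). PMEPA1, a feedback inhibitor, rose from 20.1 ± 3.92 to 38.4 ± 9.79. The ligand TGFB2 fell from 14.9 ± 3.14 to 9.56 ± 2.82 (adjusted p = 0.011, and 0.059 with no replicate block). Of 8 hedgehog pathway genes, 2 rose, 1 fell and 5 did not pass (adjusted p = 0.54; 2 higher and 1 lower adjusted over the list alone). The co-receptor gene GAS1 fell from 27.7 ± 4.94 to 18.6 ± 5.34 (adjusted p = 0.050 with no replicate block). Among 8 genes of the Hippo pathway and its targets, 0 rose, 3 fell and 5 did not pass (adjusted p = 0.12; 1 higher and 4 lower adjusted over the list alone). Without embryo 3 that list had camera adjusted p = 0.043, and with the haemoglobin covariate 0.0098, both at the preset correlation. With an estimated correlation it had adjusted p = 0.63 in the main fit. The kinase gene LATS2 fell from 30.3 ± 3.55 to 17.02 ± 1.72.

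Several genes of fibroblast growth factor (FGF) signalling rose. Of 7 tested ligands and receptors, 5 rose, 0 fell and 2 did not pass (5 higher and 0 lower adjusted over the list alone). The FGF ligand and receptor list had adjusted p = 0.0011 by camera and adjusted p = 0.42 with an estimated correlation. Beside FGF8, FGF19 rose from 30.1 ± 7.71 to 47.2 ± 7.32 and FGF13, an intracellular member of the family, from 7.54 ± 1.08 to 18.5 ± 3.84 (log2 change 1.17). Of 11 targets of the ERK kinases, 3 rose, 0 fell and 8 did not pass (6 higher and 0 lower adjusted over the list alone). The ERK target list had adjusted p = 0.0024 by camera and adjusted p = 0.42 with an estimated correlation. The ERK phosphatase DUSP6 rose from 22.7 ± 5.81 to 56.04 ± 7.26 (log2 change 1.29, adjusted p = 0.00019). The feedback inhibitors SPRY1 and SPRY2 rose from 30.3 ± 3.98 to 51.1 ± 3.61 and from 57.7 ± 4.76 to 93.5 ± 9.597. Of 9 immediate early genes, 6 rose, 0 fell and 3 did not pass (6 higher and 1 lower adjusted over the list alone). The immediate early list had adjusted p = 0.00044 by camera and adjusted p = 0.52 with an estimated correlation. The AP-1 subunit JUN rose from 23.97 ± 1.15 to 56.1 ± 9.77 (log2 change 1.18) and the zinc finger factor KLF6 from 14.9 ± 0.973 to 30.1 ± 3.96. EGR1 and FOS lay below the level tested: EGR1 was at 1.07 ± 0.442 and 7.09 ± 1.11 and FOS at 1.85 ± 0.449 and 2.59 ± 0.147. Haemoglobin genes were higher in 4 of the same 5 operated retinas; with their level as a covariate the calls of these 3 lists by camera held.

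**Figure D2:**
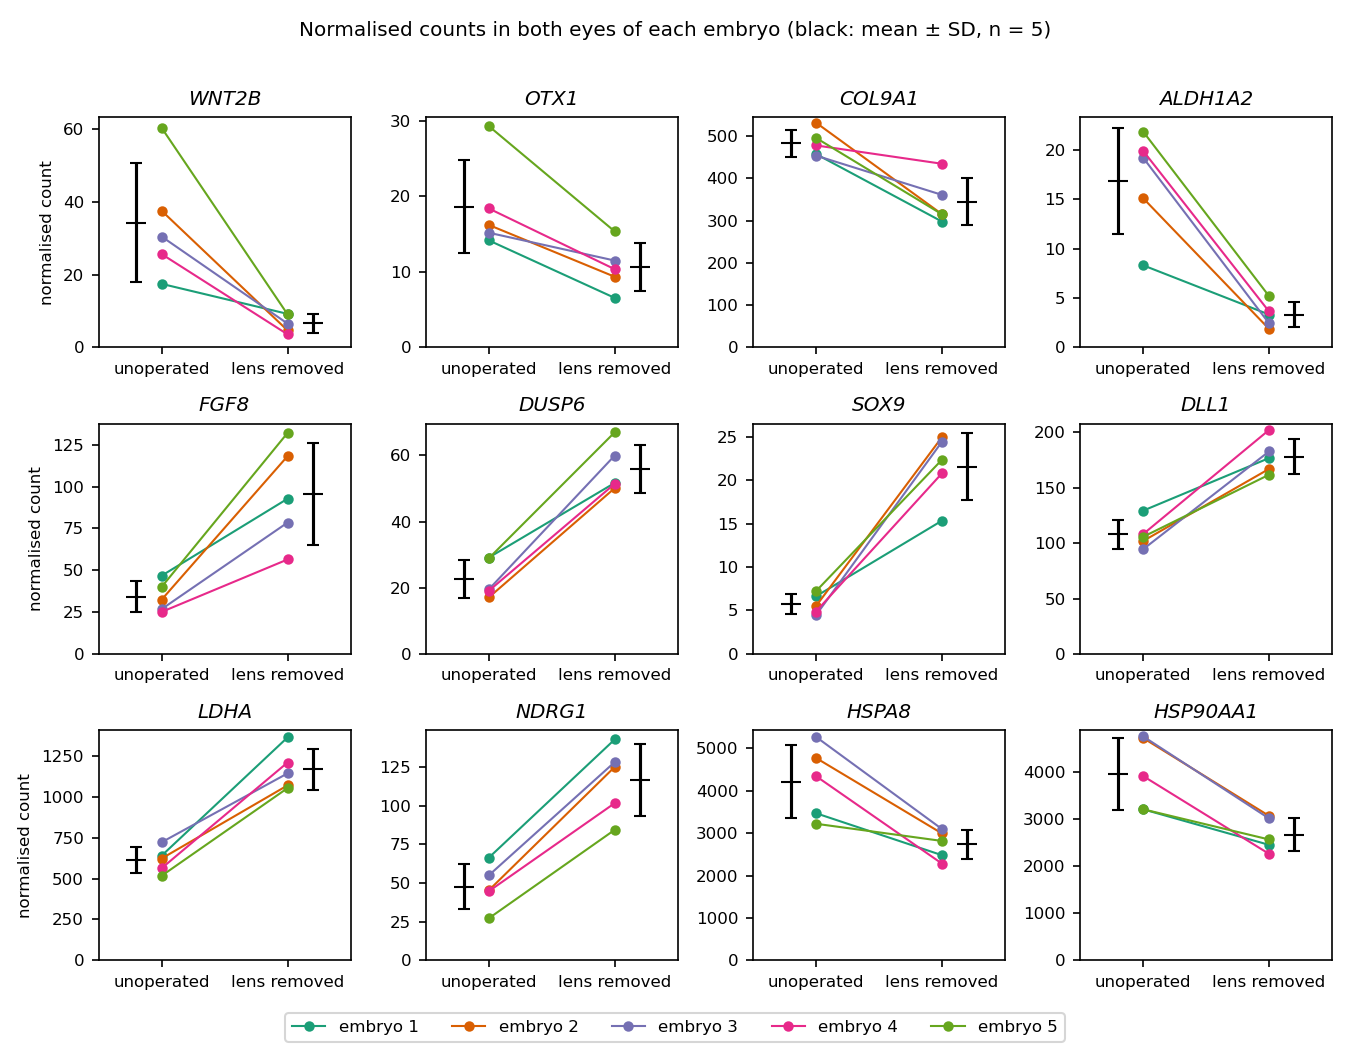
Normalised read counts of 12 genes in the control and operated retina of each embryo (points joined by lines) with the group mean ± SD (n = 5). WNT2B, OTX1, COL9A1, ALDH1A2, HSPA8 and HSP90AA1 were lower after lens removal and FGF8, DUSP6, SOX9, DLL1, LDHA and NDRG1 higher, for example DUSP6 at 22.7 ± 5.81 and 56.04 ± 7.26.

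More neural genes rose than fell, in lists that share members and so are not independent. DLL1 and HES6 stand in both the Notch and the neurogenesis list, and HES5 in both the Notch and the progenitor list. Of 12 tested Notch pathway genes, 8 rose, 0 fell and 4 did not pass (8 higher and 0 lower adjusted over the list alone). The Notch list had adjusted p = 9.7e-05 by camera and adjusted p = 0.52 with an estimated correlation. The ligand gene DLL1 rose from 108 ± 13.03 to 178 ± 15.8 (log2 change 0.72) and NRARP, a feedback regulator of Notch, from 45.6 ± 8.998 to 80.8 ± 9.703. Among 20 progenitor genes, 10 rose, 2 fell and 8 did not pass (12 higher and 2 lower adjusted over the list alone). The progenitor list had adjusted p = 0.00094 by camera and adjusted p = 0.52 with an estimated correlation. SOX9 rose from 5.73 ± 1.16 to 21.6 ± 3.86 (log2 change 1.74, adjusted p = 0.00022) and RAX from 39.99 ± 10.6 to 66.4 ± 14.5. PAX6 fell from 357 ± 34.2 to 272 ± 16.5 (adjusted p = 0.0061). Among 12 neurogenesis genes, 6 rose, 0 fell and 6 did not pass (7 higher and 0 lower adjusted over the list alone). The neurogenesis list had adjusted p = 0.0011 by camera and adjusted p = 0.52 with an estimated correlation. HES6, a gene of early neurons, rose from 11.6 ± 3.37 to 17.99 ± 6.12 (log2 change 0.56). ATOH7, which ganglion cells need, was at 28.8 ± 9.03 and 26.9 ± 6.76 (adjusted p = 0.65). Of 12 ganglion cell genes, 3 rose, 0 fell and 9 did not pass (3 higher and 0 lower adjusted over the list alone). The ganglion cell list had adjusted p = 0.0084 by camera and adjusted p = 0.52 with an estimated correlation. The growth cone gene GAP43 rose from 19.00 ± 6.19 to 32.2 ± 9.76 (adjusted p = 0.060 with no replicate block). The ganglion cell call was lost when only genes with a mean of at least 50 were tested (adjusted p = 0.085) and with the pigment covariate (adjusted p = 0.12), and fry gave adjusted p = 0.080. Pigment markers, which lie outside the neural retina, were lower on average but not in embryo 1.

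Genes that pattern the retina along its axes were compared next. Of 8 ventral genes, 6 rose, 0 fell and 2 did not pass (6 higher and 0 lower adjusted over the list alone). The ventral list had adjusted p = 0.00081 by camera and adjusted p = 0.42 with an estimated correlation. The ventral transcription factor VAX1 rose from 17.97 ± 2.52 to 28.8 ± 6.095, PAX2 from 37.7 ± 8.11 to 56.5 ± 15.03 and the receptor EPHB3 from 24.8 ± 9.99 to 48.4 ± 10.7. Of 11 dorsal genes, 4 rose, 1 fell and 6 did not pass (4 higher and 1 lower adjusted over the list alone). In the main fit that list had adjusted p = 0.14 by camera and 0.52 with an estimated correlation. Without embryo 1 camera gave adjusted p = 0.038 at the preset correlation. Among 6 optic stalk genes, 3 rose, 1 fell and 2 did not pass (adjusted p = 0.16; 3 higher and 1 lower adjusted over the list alone). Of 7 genes of the nasal and temporal retina, 1 rose, 2 fell and 4 did not pass (adjusted p = 0.54; 1 higher and 2 lower adjusted over the list alone). SALL1 rose from 49.8 ± 2.35 to 68.1 ± 3.83. The temporal factor FOXD1 fell from 36.97 ± 4.800 to 26.8 ± 6.51 (adjusted p = 0.057 with no replicate block).

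Most chaperone genes of the heat shock response fell. Of 11 tested, 0 rose, 8 fell and 3 did not pass (0 higher and 9 lower adjusted over the list alone). The heat shock list had adjusted p = 5e-05 by camera and adjusted p = 0.52 with an estimated correlation. HSPA8 fell from 4213 ± 863 to 2733 ± 344 (log2 change -0.61, adjusted p = 0.0042). HSP90AA1 fell from 3963 ± 766 to 2674 ± 354 and the mitochondrial chaperonin HSPD1 from 1304 ± 193 to 942 ± 68.7. Of 13 endoplasmic reticulum stress genes, 1 rose, 5 fell and 7 did not pass (1 higher and 6 lower adjusted over the list alone). In the main fit that list had adjusted p = 0.063 by camera and 0.52 with an estimated correlation. With only genes of a mean of at least 50 camera gave adjusted p = 0.047 at the preset correlation. The chaperone HSPA5 fell from 967 ± 41.95 to 767 ± 83.5, and its call was lost without embryo 2 (adjusted p = 0.053) or 4 (adjusted p = 0.056). Of 33 ribosomal protein genes, 0 rose, 2 fell and 31 did not pass (0 higher and 1 lower adjusted over the list alone). The ribosomal protein list had adjusted p = 0.0002 by camera and adjusted p = 0.57 with an estimated correlation. The median log2 change was -0.15, fry gave adjusted p = 0.13, and the list was not called with the pigment (adjusted p = 0.27) or mesenchyme covariate (adjusted p = 0.30). RPL23 fell from 945 ± 60.4 to 767 ± 91.2, with adjusted p = 0.059 without embryo 2 and 0.068 without embryo 4. Of 13 genes of the mitochondrial genome, 0 rose, 3 fell and 10 did not pass (adjusted p = 0.49; 0 higher and 3 lower adjusted over the list alone). CYTB was at 9035 ± 945 and 7576 ± 1029.7 and lost its call with no replicate block (adjusted p = 0.12). With chaperones lower, haemoglobin was higher in 4 of 5 operated retinas and the pigment list lower on average.

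Several genes of glycolysis and the response to low oxygen rose. Of 17 tested, 8 rose, 0 fell and 9 did not pass (10 higher and 1 lower adjusted over the list alone). The glycolysis list had adjusted p = 7.3e-05 by camera and adjusted p = 0.26 with an estimated correlation. LDHA, which encodes lactate dehydrogenase, rose from 613 ± 77.99 to 1167 ± 126 (log2 change 0.93, adjusted p = 0.00018). Also higher were the glucose transporter gene SLC2A1 (664 ± 94.1 to 1206 ± 154) and DDIT4, an inhibitor of mTORC1 (11.3 ± 1.13 to 36.5 ± 11.8, log2 change 1.56). Among 19 cholesterol synthesis genes, 4 rose, 0 fell and 15 did not pass (4 higher and 0 lower adjusted over the list alone). The cholesterol list had adjusted p = 0.0022 by camera and adjusted p = 0.52 with an estimated correlation. CYP51A1, which encodes lanosterol demethylase, rose from 267 ± 19.3 to 344 ± 47.3. This list was not called with the pigment (adjusted p = 0.24) or mesenchyme covariate (adjusted p = 0.14), and fry gave adjusted p = 0.13. Of 14 p53 and apoptosis genes, 5 rose, 1 fell and 8 did not pass (adjusted p = 0.28; 5 higher and 1 lower adjusted over the list alone). BTG2, an antiproliferative gene, rose from 11.6 ± 0.633 to 20.1 ± 2.55. Of 27 cell cycle genes, 3 rose, 6 fell and 18 did not pass (adjusted p = 0.31; 3 higher and 6 lower adjusted over the list alone). The inhibitors CDKN1B and CDKN1C rose from 48.4 ± 4.64 to 62.6 ± 3.73 and from 19.1 ± 2.91 to 27.5 ± 3.396. The replication licensing gene MCM6 fell from 421 ± 23.9 to 353 ± 7.02 (adjusted p = 0.066 without embryo 2 and 0.064 without embryo 4).

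**Figure D3:**
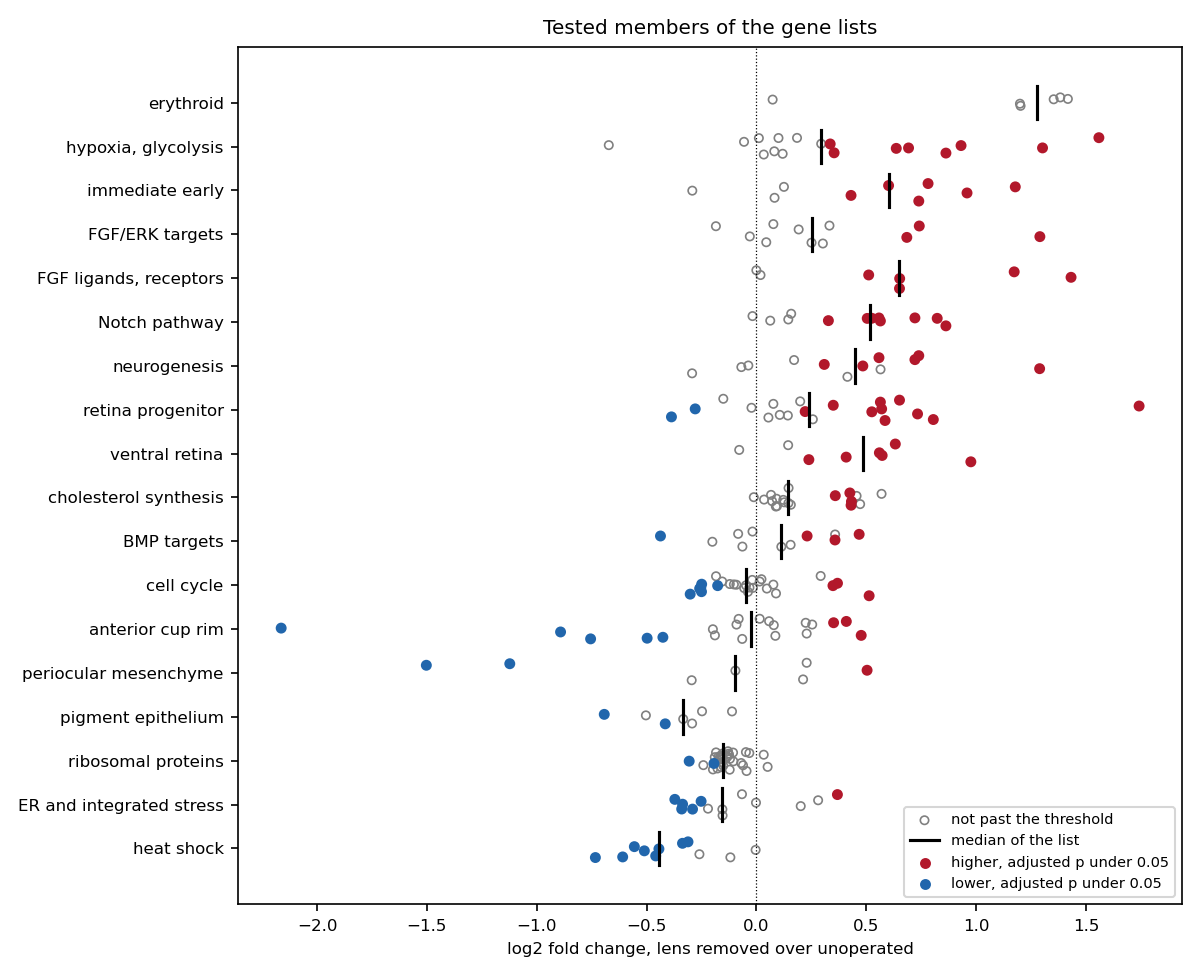
Log2 change (operated minus control) of each tested member of 18 gene lists, one point per gene, with a bar at the list's median; red points were higher and blue points lower at adjusted p under 0.05. Notch genes (12 points) lay mostly above 0 with 8 higher, and heat shock genes (11 points) mostly below 0 with 8 lower.

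Matrix and adhesion genes moved both ways. Of 23 matrix genes, 6 rose, 3 fell and 14 did not pass (adjusted p = 0.49; 6 higher and 4 lower adjusted over the list alone). EFEMP1, a fibulin, rose from 9.84 ± 1.18 to 19.7 ± 1.96, and the fibrillin FBN2 fell from 36.4 ± 14.5 to 18.5 ± 8.22 (adjusted p = 0.077 with no replicate block). Of 19 adhesion and cytoskeleton genes, 6 rose, 1 fell and 12 did not pass (8 higher and 1 lower adjusted over the list alone). The adhesion list had adjusted p = 0.0084 by camera and adjusted p = 0.52 with an estimated correlation. The adhesion molecule NCAM1 rose from 634 ± 108 to 1149 ± 178. The focal adhesion gene ZYX rose from 31.4 ± 9.96 to 63.3 ± 7.31 and the intermediate filament gene VIM from 447 ± 30.6 to 723 ± 76.1. That list was not called without a filter on low values (adjusted p = 0.075) or with the haemoglobin covariate (adjusted p = 0.077). Of 25 genes linked to eye size, 9 rose, 3 fell and 13 did not pass (9 higher and 3 lower adjusted over the list alone; adjusted p = 0.063 by camera and 0.57 with an estimated correlation). SMOC1, which is mutated in a form of microphthalmia, rose from 106 ± 14.5 to 191 ± 42.1. The list was called with quantile normalisation (adjusted p = 0.028), with only genes of a mean of at least 50 (0.040), without embryo 1 (0.038), without embryo 5 (0.010) and with the pigment (0.012) and mesenchyme covariates (0.029).

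Lists of other tissues gave the following levels. Of 7 tested pigment epithelium genes, 0 rose, 2 fell and 5 did not pass (0 higher and 2 lower adjusted over the list alone). The pigment list had adjusted p = 0.032 by camera and adjusted p = 0.52 with an estimated correlation. Without embryo 5 it had adjusted p = 0.19 and with no replicate block adjusted p = 0.085. The cation channel gene TRPM1 fell from 281 ± 36.7 to 209 ± 10.97, and MITF was at 32.1 ± 9.65 and 26.1 ± 1.98 (adjusted p = 0.18). Among 7 periocular mesenchyme genes, 1 rose, 2 fell and 4 did not pass (adjusted p = 0.7; 1 higher and 2 lower adjusted over the list alone). LUM, a matrix proteoglycan gene, fell from 17.6 ± 8.07 to 7.06 ± 1.81 (log2 change -1.12), lower in 4 of 5 embryos. FOXP1, which is broadly expressed, rose from 122 ± 19.6 to 172 ± 18.7. Of 6 red blood cell genes, 0 rose, 0 fell and 6 did not pass over all genes, with 4 higher and 0 lower adjusted over the list alone. The red cell list had adjusted p = 0.035 by camera and adjusted p = 0.52 with an estimated correlation. Without embryo 1 it had adjusted p = 0.16. The control retina of embryo 5 held more transcripts of these markers than the other controls: PMEL was at 199.8 there against 27.6 to 56.6, and HBBR at 143 against 11.5 to 18.8. Too few members for a list test were left in 5 lists. Of 4 tested lens genes, CRYBA4 rose from 86.7 ± 14.8 to 109 ± 24.7 and CRYAB fell from 27.6 ± 3.68 to 21.97 ± 3.75; with no replicate block these had adjusted p = 0.18 and 0.10. Of 4 tested endothelial genes only FLT1, a receptor for vascular endothelial growth factor, passed, falling from 24.5 ± 2.59 to 10.96 ± 1.82 (log2 change -1.10). None of 2 tested surface ectoderm genes (EPCAM at 20.3 ± 2.33 and 19.3 ± 2.07), of 3 inflammation genes (NFKB1 at 49.3 ± 6.11 and 53.9 ± 0.621) or the 1 leukocyte gene (IRF8 at 27.4 ± 2.65 and 29.5 ± 3.21) passed. Without the filter on low values, 4 of 10 inflammation genes were higher and 0 lower, 3 of 8 surface ectoderm and 4 of 14 endothelial genes were lower and 0 higher, and 0 of 6 leukocyte genes passed. In the same fit 6 of 14 pigment genes were lower and 0 higher, and 4 of 15 mesenchyme genes were lower and 1 higher.

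**Figure D4:**
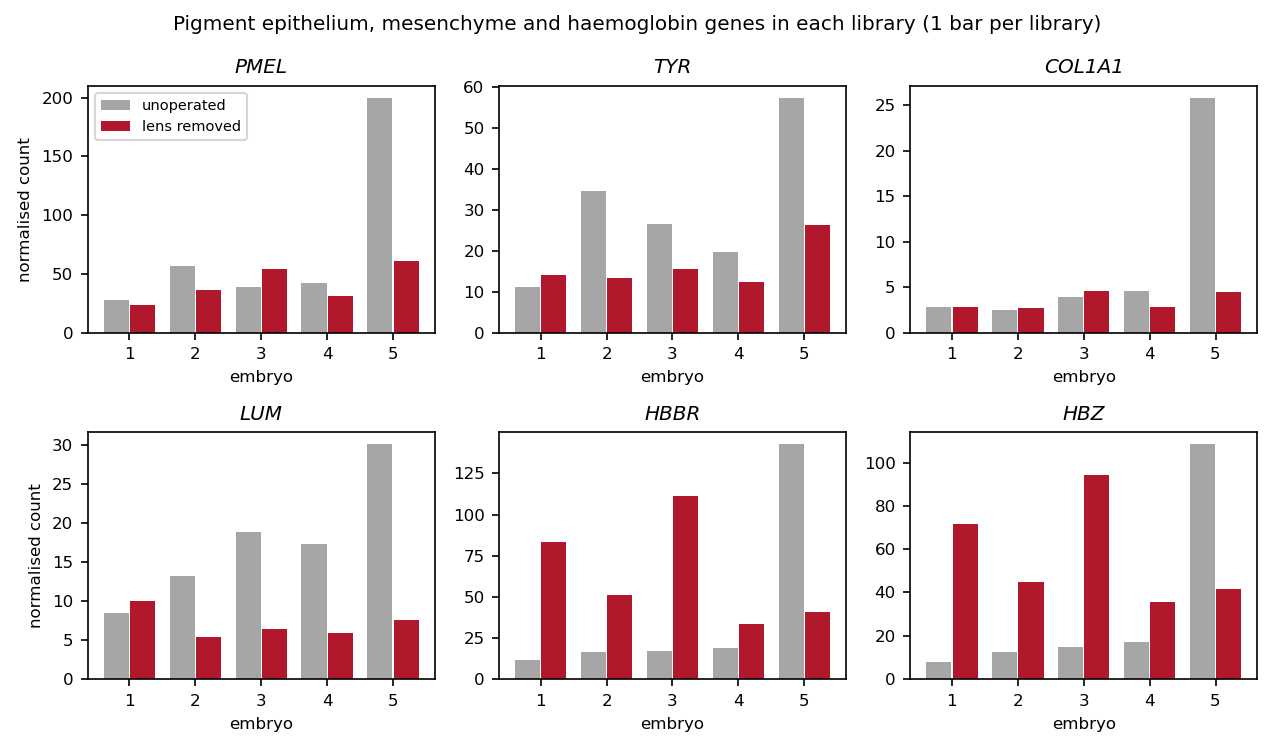
Normalised read counts of the pigment epithelium genes PMEL and TYR, the periocular mesenchyme genes COL1A1 and LUM and the haemoglobin genes HBBR and HBZ, as 1 bar per library. The control retina of embryo 5 had the highest PMEL (199.8), COL1A1 (25.8) and HBBR (143) of the 10 libraries.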

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

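The 2 tests of the control retina of embryo 5 in this part were chosen only after the result was seen. Each of 288 groups of 5 libraries, for the genes named in the report, was searched for a library whose gap to the nearest other exceeded 95% of chance gaps. Chance alone marks about 1 in 20 groups, or 14.4 of 288, and 20 stood out, of which 11 were in the control retina of embryo 5.

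In that library PTPRF was at 184 (others 80.2 to 105.0), LAMB1 at 107 (54.6 to 63.9), WNT5A at 57.1 (14.6 to 26.2), AMOTL2 at 28.9 (12.2 to 16.7) and OTX1 at 29.3 (14.2 to 18.4). PAX2 was at 52.0 (32.8 to 35.5), EPHB3 at 42.0 (18.3 to 25.1), HBBR at 143 (11.5 to 18.8) and AXIN2 at 15.4 (9.04 to 10.8). HES5 (21.0, others 42.9 to 49.9) and TP53INP1 (46.6, others 50.3 to 51.7) were lowest there. In the operated retina of embryo 5, TYR was at 26.4 (12.3 to 15.6) and DNAJA1 at 204 (147 to 159.8), while EFEMP1 at 16.3 (20.3 to 21.1) and NCAM1 at 841 (1175 to 1303) were lowest. In the operated retina of embryo 1, JUP was lowest at 75.1 (120.3 to 131) and JAG2 highest at 55.6 (44.2 to 47.5). Single libraries also stood apart for NPM3 (control of embryo 1, 179, others 206 to 215), TIMM8A (operated of embryo 4, 30.2, others 47.3 to 54.3) and CYTB (control of embryo 3, 10677, others 8409 to 8943).

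The control retina of embryo 5 had pigment, mesenchyme and haemoglobin transcripts above the other controls. RNA carried over from another of the 10 libraries is argued against as the cause of these levels, since a mixture cannot exceed its parts: 71.4% of 14 tested pigment and mesenchyme genes lay above all 9 other libraries there, against 17.5% of all tested genes, though of the mesenchyme genes alone only 3 of 7 did. A small carry-over stays open beside it: the W-linked genes HINTW, ATP5A1W and SMAD2W lay above their mean in the controls of embryos 1 and 4, as a share of 2.29%, 2.09% and 1.78% of RNA from embryos 2 and 3 would give. More pigment epithelium and mesenchyme in that dissection may explain the levels. The test took the members with a mean under 10 whose levels had not been looked at: 69.2% of 13 were at their highest control level there (4 of 6 pigment and 5 of 7 mesenchyme genes), against 37.5% of all genes with such a mean. These few genes lie near the low end. The genes that drew attention include PMEL at 199.8, DCT at 94.9, TYR at 57.4 and COL1A1 at 25.8. RNA from outside the 10 libraries was not tested, and no biological explanation was tested, since the labels name none for this embryo.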

How the results depend on the processing

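Chosen only after the result was seen were the precision weights and the 3 tissue covariates. Against 963 higher and 1112 lower genes, requiring a 2-fold change gave 56 and 11, by construction, and testing only means of at least 50 gave 412 and 814, with fewer genes tested. With no replicate block 701 and 783 genes passed, 1459 of them shared with the blocked fit; that fit ended the call of 1 list (pigment epithelium) and of 27 named genes. Leaving out 1 embryo gave 387 to 1378 higher and 301 to 1468 lower, fewest without embryo 4 (387 and 301) and embryo 2 (438 and 377). The most were called without embryo 1 (1378 and 1468). The pigment covariate gave 80 and 9, the mesenchyme covariate 134 and 29 and haemoglobin 414 and 314, mostly with wider errors: over the changed genes the median SE rose 1.77, 1.51 and 1.36 times, and the log2 change was 0.894, 0.874 and 1.01 times its value. Every gene passing both here and in an alternative kept its direction; other settings gave 858 to 1428 higher and 1068 to 1262 lower. Of 134 named genes that passed, 134 still did with either other pseudocount or the robust prior, 132 of 133 with no filter, 81 of 81 at the higher filter, 132 with trimmed means, 126 with quantile normalisation, 133 with weights, 96 to 130 without 1 embryo, and 24, 40 and 92 with the pigment, mesenchyme and haemoglobin covariates. Signs turned for genes that had not passed, and the cause was not tested: BMP4 with quantile normalisation (-0.021), without embryo 2 (-0.027; -0.027 to 0.22 without 1 embryo) and with haemoglobin (-0.18); HBBR (-0.26) and ATOH7 (0.068) with haemoglobin; EPCAM (0.069) with pigment; and IRF8 (-0.073 and -0.016) and MITF (0.17 and 0.052) with pigment and mesenchyme. For lists, camera's direction can differ from the sign of the mean log2 change given here. It turned for Wnt ligands with no filter (-0.16) and at a mean of at least 50 (0.22, adjusted p = 0.040; 0.040 to 1.00 over the planned settings), for hedgehog genes with no filter (-0.031) and with mesenchyme (-0.0041), for rim genes at the higher filter (0.020), for pigment (0.13) and mesenchyme genes (0.076) with pigment, for mesenchyme genes with mesenchyme (0.015), for matrix genes with haemoglobin (-0.030) and for mitochondrial genes with quantile normalisation (0.017) and pigment (0.028). Without 1 embryo it turned for Wnt ligands (without embryo 1 -0.24, range -0.31 to -0.23), hedgehog (without embryo 3; -0.026 to 0.18), rim (without embryo 5; -0.21 to -0.11) and mesenchyme genes (without embryo 5; -0.40 to -0.17). Tests with edgeR and DESeq2 were not run, since whole reads were not recovered. Apart from the 2-fold limit, counts fell most with the covariates and without embryos 2 and 4. In the simulation 30% of the smallest changes and 78% of 1.5-fold changes were found, and 86.0% of the genes called in the data were under 1.5-fold. The simulation called only 156 genes, against 2075 in the data, which makes its adjusted threshold stricter. These shares therefore do not carry over directly to the data, where small changes may still be missed.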

Other observations

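The genes below the level tested in the report were looked at after their values were seen, and the tests of rim and chaperone genes in this part were chosen only after the result was seen. Of 3388 genes with a mean under 10, 470 were higher and 159 lower at adjusted p under 0.05 when limma was run without the filter. Among those highest in log2 change, chosen after their values were seen, the neuronal nitric oxide synthase gene NOS1 rose from 1.23 ± 0.433 to 15.9 ± 6.62 and the ERK phosphatase gene DUSP5 from 0.199 ± 0.0604 to 7.05 ± 3.01. LTBP2, which encodes a matrix protein of the ciliary zonule, rose from 1.46 ± 0.397 to 12.3 ± 2.898, the stress factor ATF3 from 3.16 ± 0.642 to 16.1 ± 3.12, and EGR1, a named gene of the report, from 1.07 ± 0.442 to 7.09 ± 1.11. GDF11, a TGF-beta family ligand, rose from 3.498 ± 1.06 to 13.2 ± 2.85 and PAX5 from 0.772 ± 0.285 to 7.93 ± 2.74. Among those lowest, the phosducin gene PDC fell from 5.15 ± 0.977 to 0.544 ± 0.582, BNC1 from 6.66 ± 1.79 to 1.13 ± 0.536, and KERA, a proteoglycan gene of corneal stroma, from 11.4 ± 2.78 to 3.92 ± 1.903. The hedgehog inhibitor gene HHIP fell from 5.95 ± 3.02 to 1.99 ± 0.296, and LMX1B, which acts in anterior segment mesenchyme, from 4.73 ± 1.97 to 1.58 ± 0.768, the latter in 4 of 5 embryos.

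Nucleolar genes fell together. After NPM3, NOP16, NAT10 and RSL1D1 had been seen to fall, with NPM1 and NCL also looked at, a list of 48 other nucleolar and ribosome biogenesis genes was written without those 6, and its test was stated before it was run. Of 45 tested, 36 fell, 0 rose and 9 did not pass (0 higher and 38 lower adjusted over the list alone), with a median log2 change of -0.35. NOP2, chosen after its values were seen, fell by 0.55 on the log2 scale, NOLC1 by 0.52 and DDX21 by 0.52. Camera gave p = 9.09e-18 at the preset correlation, and p = 0.018 with an estimated correlation, or adjusted p = 0.32 over the lists. The list was not tested with the tissue covariates or with an embryo left out. The ribosomal protein list lost its camera call with the pigment (adjusted p = 0.27) and mesenchyme covariates (adjusted p = 0.30). A hypothesis is that lens removal may be followed by lower ribosome production in the retina; it was found and tested on the same libraries, and ribosome synthesis itself was not measured.

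The rim genes OTX1, COL9A1, WNT2B, ZIC1 and GJA1 had a mean log2 change of -0.95. Less pigment epithelium in the operated dissections cannot be told apart from a change in rim genes. Pigment genes were compared with rim genes, both chosen in each embryo as those called lower without it. The difference was 0.686 (SD 0.134 between embryos), but it rests on TRPM1 alone in embryos 2, 4 and 5, whose level was 325 in the control of embryo 5 against 244 to 309 in the others, where PMEL was at 199.8 against 27.6 to 56.6. Over the whole pigment list it was 0.580 (SD 0.372), though -0.070 in embryo 5. Less mesenchyme cannot be told apart either: chosen likewise, mesenchyme genes differed from rim genes by -0.373 (SD 0.902), from 0.91 in embryo 1 to -1.27 in embryo 5, with 1 to 3 genes per embryo. Over the tested mesenchyme list without NR2F2, which is also in the rim list, the difference was 0.567 (SD 0.387). The choice of markers thus decides its sign. The form and the bounds of these comparisons were set with the changes per embryo known. With the pigment covariate WNT2B moved from -2.16 (SE 0.24) to -1.36 (SE 0.25), so part of its fall may come with pigment tissue. OTX1 (-0.75, SE 0.10, to -0.77, SE 0.19) and COL9A1 (-0.50, SE 0.090, to -0.44, SE 0.16) lost their calls with wider errors, while GJA1 kept its own (-0.89, SE 0.15). That fit called only 89 genes, against 2075 without the covariate, so its adjusted threshold was stricter as well. A smaller share of rim tissue in the operated dissections cannot be told apart from a change within it: 25% of the tested rim list fell and 15% rose, but the bounds of that test were set with the counts known, and several members are also expressed outside the rim. A fall of rim expression after loss of the lens, and an effect of the dorsal slit, stay open.

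Of 11 chaperone genes 8 fell; the list passed at the preset correlation (adjusted p = 5e-05) and not with an estimated correlation (adjusted p = 0.52). The authors' scaling of the libraries is argued against, since the mean log2 change was -0.39 as deposited and -0.362 with quantile normalisation, and lay between -0.46 and -0.31 over the planned settings, with adjusted p of 1.5e-06 to 0.00011 at the preset correlation. The time out of the egg and the order in which the eyes were dissected could also move these genes, and were not tested, since no label gives them. The same holds for a response to the operation itself, which the design confounds with loss of the lens.

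The number of changed genes was compared with other ways to part the 10 libraries into 5 and 5. Of 100 splits drawn from 126, 3 gave at least as many genes in 1 direction as were higher (963), the real one included, and 3 as many as were lower (1112); the highest other count was 1229, and most of the 100 splits leave some pairs of eyes in the same group. The 2 others parted only embryos 2, 3 and 4, and did so along the real operation, so they hold the real contrast in those embryos. Of the 16 splits that part all 5 pairs, the 15 others called 0 genes with limma, with 5 to 2427 genes at an unadjusted p under 0.05 against 3399 in the real split. Each of the 15 reverses the operation in some embryos, so a real effect would widen its errors. Their 0 calls therefore do not show what chance alone gives, and 16 splits are too few for a share under 0.05.

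The changes of single embryos were correlated across genes, which are not independent replicates, at 0.80 to 0.85 among embryos 2, 3 and 4 and at 0.12 to 0.57 in the pairs with embryos 1 and 5. The W-linked gene HINTW was at 988 and 953 in the control and operated retinas of embryo 2 and at 1088 and 966 in embryo 3. It was at 6.04 and 8.61 in embryo 1, 5.45 and 3.13 in embryo 4, and 28.5 and 8.94 in embryo 5.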
